A study of Mus musculus with 6 samples.

How the data were processed

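ATAC-seq libraries were made by the submitters from lung ILC2s sorted as Lin-CD25+ST2+ cells from wild-type mice, female unless otherwise stated, with a Tn5 library kit. There were 2 libraries for each of 3 groups (naive, effector and memory), each from a separate pool of 2 to 4 mice and about 50000 cells, so libraries are biological replicates. The deposited table holds raw counts per region for 57203 regions shared by all 6 libraries, and these counts were used as deposited, with no value changed. Per the submitters' processing notes the tools were fastp, Bowtie2 2.5.3, MACS2, bedtools 2.31.1, ChIPseeker 1.28.3, deepTools 3.5.4 and edgeR 3.34.0 on mm10. How the shared regions were merged, which tool counted, whether reads, fragments or shifted insertions were counted, which duplicate and mitochondrial filters were applied, and whether starts count from 0 or 1 are not given in the sources used here.

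Library totals in the regions ran from 11995095 to 20591102 counts. The region with the highest count held 0.227% to 0.316% of a library. Wilson 95% intervals of the shares of counts reported for single libraries were no wider than 0.028 percentage points on either side. They cover counting error only, since reads without molecular identifiers are not independent molecules. The common dispersion was 0.0283, and the median biological coefficient of variation over regions was 19%.

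Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Regions were filtered with filterByExpr by group, which left 56007 and removed 1196. Libraries were scaled by TMM, dispersions were trended, and a quasi-likelihood model with a term per group was fitted to all 6 libraries with robust estimation and 3 residual degrees of freedom. Each pair of groups was compared with a two-sided quasi-likelihood F test, and a region was called at a Benjamini-Hochberg adjusted p under 0.05 over the tested regions, with no minimum fold. Standard errors are the log2 fold change divided by the square root of F. Levels are TMM-scaled CPM, counts divided by the effective library size, with the SD of 2 libraries. For named regions with 20 or fewer counts over the libraries of a group, the text gives the ratio of scaled counts with its exact 95% counting interval. Principal components and library correlations used log2 CPM with a prior count of 2.

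Regions were assigned to the nearest of 21900 protein-coding genes of GRCm38.p6 (mm10) within 100 kb, and 54123 regions (94.6%) received a gene. A region overlapping or within 1 kb of either end of a gene was counted as a gene end region, 24.3% of all regions, against 9.0% after shifting regions by 50 kb. The gene table holds no strand, so the planned distance to a transcription start and the planned promoter share were replaced by these. A region's nearest gene need not be the gene it acts on. Shares at gene ends of called and not called regions were compared with Fisher's exact test, two-sided.

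There were 20 gene lists with 315 genes, of which 289 had a region. They cover type 2 cytokines and effector products, ILC2 lineage transcription factors, alarmin, cytokine and costimulatory receptors, AP-1, NF-kB and immediate early genes, inhibitory receptors and regulatory genes, neuropeptide, prostaglandin and leukotriene receptors, residence and migration, cell cycle, glycolysis and lipid metabolism, lymphocyte memory and quiescence, the SWI/SNF complex, the interferon response, markers of T cells, B cells, NK cells and ILC1, ILC3s, myeloid cells, mast cells and basophils, and lung epithelium, endothelium and stroma, and housekeeping genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 20 lists of a comparison, and with camera at an estimated correlation and fry as alternatives. Fry tests whether the regions of a list move on balance one way and does not compare them with other regions. List medians were also set against 10000 random lists of regions matched on mean count.

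The text names, per comparison and direction, the 10 regions with the smallest adjusted p among calls of at least 2-fold, best region per gene. Regions with no gene assigned were not ranked. The text further names up to 4 genes per list with the smallest adjusted p among calls, and the region with the highest mean count of each of 12 genes (Il5, Il13, Il4, Areg, Gata3, Rora, Il1rl1, Il17rb, Klrg1, Icos, Tcf7 and Smarca4). Genes of a list summarised by count may be left out. The groups, tests, lists, naming rule and all alternatives but the last named next were fixed before the data were examined. The alternatives were RLE size factors, total counts alone, a loess offset on abundance (span 0.3), no low-count filter, DESeq2 1.42.0, no robust estimation, only the 2 groups compared, the replicate number as a block, each library left out in turn, an adjusted p under 0.01, at least 2-fold changes, and, chosen after seeing the data, TMM on the 20% of regions with the highest mean count. Where a group was left with 1 library, that library was assumed to vary like the others.

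The pipeline was tested on simulated data built from these counts with known changes. The test of effector against naive cells recovered 3 of 67 1.5-fold changes (4.5%), 27 of 66 2-fold changes (40.9%) and 53 of 66 4-fold changes (80.3%). Of the 55868 regions tested, 15 unchanged ones were called too, and a comparison without changes gave 10 calls. With few changed regions the adjusted p threshold is stricter than where many change. These shares therefore need not hold for the measured effector cells. Shared naive controls were checked with 100 simulated sets without group differences. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Motif content and corrections for GC content and width were not run, since they need a genome sequence, and none was used here.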

Results

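Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 inserts into open DNA, in group 2 innate lymphoid cells (ILC2s) sorted from mouse lung. ILC2s are tissue-resident lymphocytes that answer alarmins such as IL-33 with type 2 cytokines. The design set 3 states side by side: naive cells from mice given PBS for 3 days, effector cells from mice given 30 µg of the protease allergen papain per day for 3 days, and memory cells from mice given the same papain course and then rested for 2 months. Each state had 2 libraries, and each library came from a separate pool of about 50000 cells from 2 to 4 wild-type mice. The series title names Brg1, the ATPase of the SWI/SNF remodelling complex that Smarca4 encodes, and no Brg1-deficient library was among the 6. The total count in the shared regions was 12964912 and 16910329 in the naive libraries, 14872821 and 16397249 in the effector libraries, and 11995095 and 20591102 in the memory libraries. Counts covered 57203 regions of mm10 with a median width of 1203 bp, of which 56007 were tested.

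The effector libraries stood apart from the other 4. Principal component 1 held 59.4% of the variance and placed effector libraries at 145 and 112.5 and the naive and memory libraries between −71.9 and −52.1. Principal component 2 held 15.8% and placed replicate 1 above replicate 2 in every group. The values of replicates 1 and 2 were 85.0 and −3.7 for naive, 11.3 and −17.3 for effector and 0.8 and −76.0 for memory libraries. No label says what libraries with the same replicate number share. Across regions, which are not independent replicates, Pearson's r of log2 CPM was 0.967 to 0.969 within a group and 0.899 to 0.936 between effector and naive libraries. Between memory and naive libraries it was 0.951 to 0.969, so some memory and naive libraries resembled each other as closely as replicates did. The 50% of regions with the lowest mean count held 9.07% and 9.31% of the counts in the effector libraries, against 6.49% and 6.96% in the naive and 5.89% and 6.34% in the memory libraries.

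**Figure D1:**
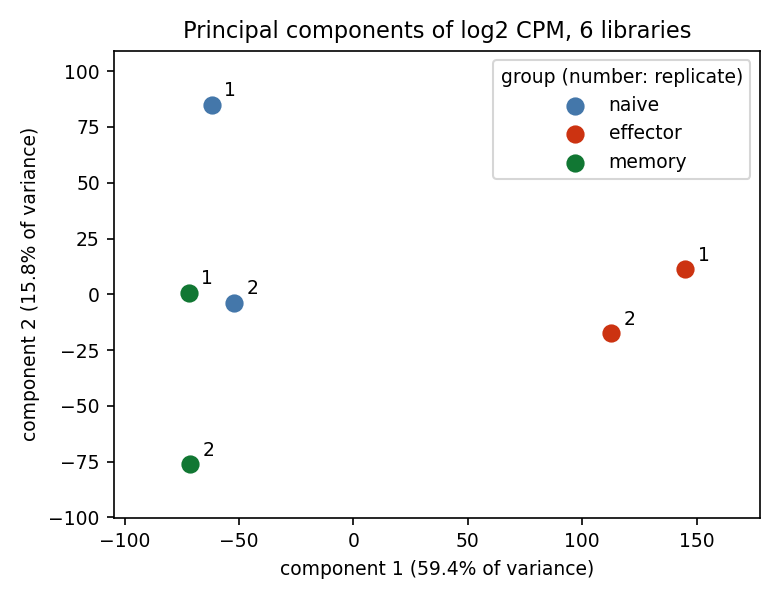
Principal components 1 and 2 of the log2 CPM of the 6 libraries, with each axis labelled by its percent of variance and each point a library coloured by group. The 2 effector libraries lie at 145 and 112.5 on component 1, and the naive and memory libraries lie between −71.9 and −52.1.

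The comparison of effector with naive cells asks how 3 days of papain change the accessible genome. Many regions opened, and most of those that opened lay away from gene ends. A region 22.5 kb from Pparg, which encodes a lipid-activated nuclear receptor, rose from 2.44 ± 0.62 to 18.6 ± 2.98 CPM (TMM-scaled, SD, n = 2 per group). A region inside Havcr2, which encodes the inhibitory receptor TIM-3, rose from 8.48 ± 0.553 to 30.2 ± 4.91, and a region inside Il1rl1, which encodes the IL-33 receptor ST2, rose from 14.2 ± 0.759 to 41.3 ± 13.9. A region 18.9 kb from Adora2a, which encodes the adenosine receptor, fell from 29.3 ± 0.962 to 14.1 ± 1.85. In all, edgeR's quasi-likelihood test called 6449 regions more accessible and 2791 less accessible at an adjusted p under 0.05. At least 2-fold changes made up 5342 of the gains and 387 of the losses.

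By the smallest adjusted p among gains of at least 2-fold with a gene assigned, the leading regions lay in or near E130308A19Rik, Tprg, Adarb1, Itpr1, Lactb, Frzb, Col18a1, Gtsf1l, Ngef and Prkg1. Their log2 fold changes ran from 2.92 to 5.70 and their edgeR adjusted p from 7.29e-07 to 1.63e-06. The region inside Itpr1 (6:108337673-108339144), which encodes an IP3-gated calcium channel, rose by 2.94 ± 0.21 on the log2 scale (SE). The region inside Prkg1 held 8 counts over both naive libraries and 467 over both effector libraries, a ratio of 52.4 with a 95% counting interval of 26.4 to 122. The leading losses lay in or near Lor, Ptp4a1, Erich2, Galnt6, Slc27a6, Ptcd3, Ppm1k, Lclat1, Ccdc71l and Sugct, with log2 fold changes from −1.21 to −1.02 and edgeR adjusted p from 6.68e-05 to 0.00028. The region at Lor (3:92080353-92083183), a gene of the epidermal cornified envelope, fell from 142 ± 12.3 to 68.7 ± 6.84 CPM. Coordinates are printed as deposited for mm10, and the sources used here do not state whether starts count from 0 or 1.

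The balance of gains and losses moved with abundance and with the scaling. Across 5 equal bins of mean count the median log2 fold change ran from 0.54 in the lowest to −0.20 in the highest, and gains were 69.8% of calls with TMM, 82.5% with total counts alone (7261 more, 1535 less) and 92.1% with TMM on the 20% highest regions (8660 more, 739 less). That last scaling, chosen after seeing the data, shifted the median of all regions by 0.20, and a loess offset on abundance gave 5256 more and 1625 less. The libraries also weighed on the counts. Calls of at least 2-fold numbered 2339 more and 73 less without effector replicate 1, 4268 and 823 without effector replicate 2, 5897 and 216 with total counts, 6762 and 126 with TMM on the highest regions and 3907 and 707 with the loess offset. At any fold, without effector replicate 1 there were 2530 gains and 377 losses, without naive replicate 1 there were 4014 and 828, and without naive replicate 2 there were 4671 and 1688.

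Regions of ILC2 transcription factors and of alarmin and cytokine receptors opened more often than they closed. So did tested regions in general, of which 11.5% rose and 5.0% fell. Of 366 regions assigned to the 18 genes of the ILC2 lineage transcription factor list, 53 rose and 6 fell (53 and 6 when adjusted over the list alone). Besides Pparg (6:115512868-115513986, log2 2.91 ± 0.28 SE, edgeR adjusted p = 8.5e-06), a region inside Tcf7, which encodes the developmental factor TCF-1, rose by 2.05 ± 0.21 (11:52260729-52262295, edgeR adjusted p = 1.16e-05). Regions 7.3 kb from Ets1 and 37.4 kb from Bhlhe40, both genes of transcription factors, rose by 2.44 ± 0.28 and 1.86 ± 0.23. Of 139 regions of alarmin, cytokine and costimulatory receptors, 18 rose and 4 fell (18 and 4 when adjusted over the list alone). The region inside Il1rl1 (1:40412390-40414027) rose by 1.54 ± 0.21, and regions near Il4ra, the IL-4 receptor chain, and Il2ra, which encodes CD25, rose by 2.51 ± 0.39 and 1.88 ± 0.32. The region at an end of Il1rap, the accessory chain of the IL-33 receptor, fell by 0.62 on the log2 scale (SE 0.13, edgeR adjusted p = 0.00397), and this call was lost without naive replicate 1 (adjusted p = 0.0636) or effector replicate 1 (adjusted p = 0.059). Neither list was called by camera against other regions, with adjusted p of 0.387 and 0.822.

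Regions at genes of type 2 cytokines and other effector products changed in both directions, with more gains than losses, as among all tested regions. Of 113 such regions, 22 rose and 6 fell (25 and 6 when adjusted over the list alone), with a camera adjusted p of 0.387. A region 21.8 kb from Csf2, which encodes the cytokine GM-CSF, rose by 1.41 ± 0.21 on the log2 scale (SE, edgeR adjusted p = 0.000236). A region at an end of Gzmb, which encodes granzyme B, rose by 1.98 ± 0.39. A region 76.0 kb from Il6 held 12 counts over the naive and 121 over the effector libraries, a ratio of 9.06 (95% counting interval 5.00 to 18.0). A region at an end of Klrg1, an inhibitory receptor of activated ILC2s, rose from 44.2 ± 1.90 to 75.4 ± 12.5 CPM (edgeR adjusted p = 0.00223, but 0.0604 without effector replicate 1).

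Of the most covered regions of 12 genes chosen in advance, those of Klrg1, Il1rl1 and Areg were called and the others were not. Among those at Il5, Il13, Il4, Gata3, Rora, Il17rb, Icos, Tcf7 and Smarca4, edgeR gave log2 differences between −0.73 and 0.27 and adjusted p between 0.0788 and 0.965. The region at an end of Il5, the eosinophil growth factor, measured 58.5 ± 4.52 CPM in naive and 58.0 ± 2.89 in effector cells. For Il13 the values were 38.4 ± 0.701 and 46.5 ± 3.33, and for the region inside Gata3, the lineage-defining factor of ILC2s, 104 ± 5.55 and 105.0 ± 9.96. The region of Klrg1, given above, rose by 0.77 ± 0.15 on the log2 scale (SE), and its call was lost without effector replicate 1. The most covered region of Il1rl1 rose by 0.47 ± 0.13 on the log2 scale (SE, edgeR adjusted p = 0.0175), a call lost without naive replicate 1 (adjusted p = 0.163), naive replicate 2 (0.0552) or effector replicate 1 (0.14). That of Areg, which encodes amphiregulin, fell by 0.39 on the log2 scale (edgeR adjusted p = 0.0484), a call lost without naive replicate 1 (adjusted p = 0.209), naive replicate 2 (0.128) or effector replicate 1 (0.358) and under total counts alone (0.134), the loess offset (0.37), TMM on the highest regions (0.347) and without robust estimation (0.0552).

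Inhibitory, activation and quiescence genes also gained more regions than they lost. Of 163 regions of inhibitory receptors and regulatory genes, 29 rose and 8 fell (34 and 8 when adjusted over the list alone). These included Ctla4, an inhibitory receptor (1.52 ± 0.20 on the log2 scale, SE), Il10, an anti-inflammatory cytokine (2.01 ± 0.29), and Prdm1, which encodes the repressor Blimp-1 (2.70 ± 0.42). Of 221 regions of AP-1, NF-kB and immediate early genes, 29 rose and 8 fell (29 and 9 when adjusted over the list alone), among them Atf3 (0.92 ± 0.15), Myc (1.89 ± 0.30), Fos (1.30 ± 0.21) and Rel (2.09 ± 0.35), all genes of transcription factors. Of 243 regions of lymphocyte memory and quiescence genes, 41 rose and 14 fell (44 and 17 when adjusted over the list alone), with a region near Bach2, a repressor of effector programmes, at 1.99 ± 0.20, the antiproliferative Btg1 at 3.02 ± 0.33 and Id3 at 3.02 ± 0.40. Camera's adjusted p for these lists was 0.387, 0.822 and 0.822.

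Single regions of residence genes and of neuropeptide receptor genes were called in both directions. Of 126 regions of residence and migration genes, 19 rose and 9 fell (19 and 9 when adjusted over the list alone). A region near Rgs1, a regulator of G-protein signalling, rose by 1.82 ± 0.19 on the log2 scale (SE), and others rose near the chemokine receptor gene Ccr4 (2.07 ± 0.26) and the integrin genes Itga1 (3.04 ± 0.39) and Itgae (1.64 ± 0.21). Of 97 regions of neuropeptide, prostaglandin and leukotriene receptors, 7 rose and 7 fell (7 and 7 when adjusted over the list alone). A region inside Vipr2, which encodes a receptor of vasoactive intestinal peptide, rose by 1.43 ± 0.19. Regions near Adora2a and near Ramp3, a chaperone and partner of the calcitonin-like receptor, had log2 fold changes of −1.05 ± 0.17 and −0.82 ± 0.14. Camera's adjusted p was 0.822 and 0.387.

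Of 88 cell cycle regions, 10 rose and 3 fell (9 and 3 when adjusted over the list alone), with the kinase gene Cdk6 at 1.69 ± 0.20 on the log2 scale (SE) and the cyclin gene Ccne1 at 2.29 ± 0.35. A region inside Tyms, the thymidylate synthase gene, held 8 naive and 112 effector counts, a ratio of 12.6 (95% counting interval 6.17 to 29.8). Of 111 glycolysis and lipid regions, 7 rose and 3 fell (6 and 3 when adjusted over the list alone). A region inside Slc7a5, an amino acid transporter, rose by 2.14 ± 0.25 and another near Hif1a, the hypoxia factor, by 1.38 ± 0.25. The call inside Pfkp, a phosphofructokinase gene (1.34 ± 0.33), was lost without naive replicate 1 (edgeR adjusted p = 0.0668) or effector replicate 1 (0.0957). Of 97 regions of SWI/SNF genes, 8 rose and 1 fell (6 and 0 when adjusted over the list alone). The region inside Arid1b, a subunit gene, rose by 1.96 ± 0.34 (17:5165037-5167325, edgeR adjusted p = 0.000809). Weak calls inside Arid1a and Smarcc1 (edgeR adjusted p = 0.0432 and 0.0436) were lost under DESeq2 (0.119 and 0.117), under the loess offset (0.15 and 0.19) and without several single libraries (up to 0.284 and 0.212). Of 32 interferon response regions, 3 rose and 0 fell (3 and 0 when adjusted over the list alone). Of these, a region near Irf1 had 1.58 ± 0.43 and lost its call without naive replicate 1 (edgeR adjusted p = 0.15) or effector replicate 1 (0.171). Camera's adjusted p for these 4 lists was 0.822, 0.822, 0.877 and 0.822.

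Markers of other cell types were tested in the same way, and none of the 7 lists was called by camera. Of 33 myeloid regions 6 rose and 0 fell (7 and 0 when adjusted over the list alone), with a region near Itgam, which encodes CD11b, going from 1.72 ± 0.0571 to 8.61 ± 1.97 CPM and a region near Cebpb from 4.88 ± 0.00619 to 15.2 ± 1.37. A region at an end of Itgax, which encodes CD11c, had 2 naive and 38 effector counts, a ratio of 17.1 (95% counting interval 4.41 to 146), and lost its call without naive replicate 2 (edgeR adjusted p = 0.123), without effector replicate 1 (0.13), without effector replicate 2 (0.0892), under DESeq2 (0.0545) and under the loess offset (0.101). Of 55 T cell regions 4 rose and 6 fell (5 and 6 when adjusted over the list alone). Regions at Ikzf2, which encodes Helios, and Cd5 rose by 3.36 ± 0.32 and 1.30 ± 0.22 on the log2 scale (SE). Of 17 ILC3 regions 2 rose and 1 fell (2 and 1 when adjusted over the list alone). The fall was inside Il1r1, the IL-1 receptor gene, from 36.8 ± 6.38 to 22.5 ± 2.49 CPM, and was not called without naive replicate 2 (edgeR adjusted p = 0.0887) or effector replicate 1 (0.0798). The gains, near the cytokine genes Il17f and Il22, were not called without naive replicate 1 (0.0674 and 0.147), naive replicate 2 (0.0895 and 0.131) or effector replicate 1 (0.0525 and 0.264), nor was Il17f without effector replicate 2 (0.108) or Il22 under DESeq2 (0.0568).

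Of 19 B cell regions 2 rose and 0 fell (0 and 0 when adjusted over the list alone), of 20 NK cell and ILC1 regions 1 rose and 0 fell (1 and 0), of 23 mast cell and basophil regions 1 rose and 4 fell (1 and 5), of 59 lung epithelium, endothelium and stroma regions 5 rose and 1 fell (3 and 1), and of 50 housekeeping regions 4 rose and 2 fell (4 and 2). Regions near Pecam1, an endothelial adhesion gene, and Ywhaz were among the gains. The first held 10 naive and 99 effector counts, a ratio of 8.89 (95% counting interval 4.64 to 19.1), and the second rose by 1.74 ± 0.29 on the log2 scale (SE). Over all tested regions 11.5% rose and 5.0% fell. Camera called 0 of 20 lists (lowest adjusted p 0.336, for mast cells and basophils), as it did with an estimated correlation, and fry called the myeloid list (adjusted p = 0.0284). Against random lists matched on mean count, which treat regions as independent, the medians of type 2 genes (0.15), ILC2 transcription factors (0.14) and receptors (0.05) lay at percentile 100, those of residence and inhibitory genes at 98.8 and 98.6, and that of mast cells and basophils (−0.29) at 0.4. The other 14 lay within the central 95%. Median and mean differed in sign for the AP-1 and NF-kB, memory and quiescence, NK cell and housekeeping lists, for example −0.06 and 0.15 for AP-1 and NF-kB. Camera's direction was downwards for the glycolysis, interferon and T cell lists, whose medians and means were above 0.

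**Figure D2:**
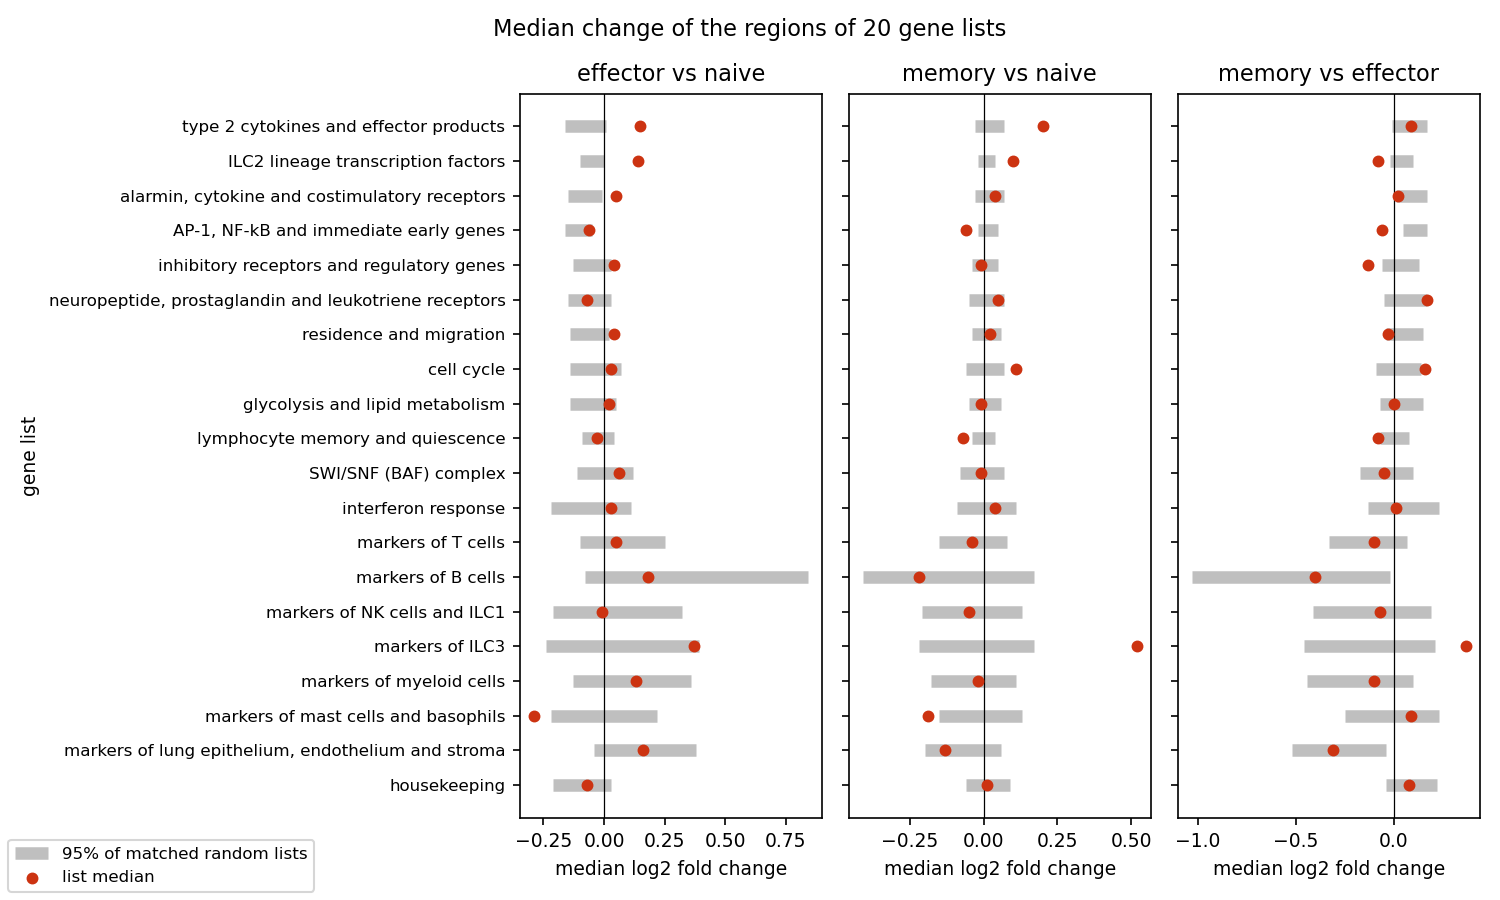
Median log2 fold change of the regions of each of the 20 gene lists in each comparison (points), with the central 95% of the medians of 10000 random region lists of the same size and matched mean count (bars). The type 2 list lies at 0.15 in effector against naive cells, 0.20 in memory against naive cells and 0.09 in memory against effector cells, and regions of a list are not independent of each other.

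Gained regions were mostly away from gene ends. Only 402 of the 6449 gained regions (6.2%) overlapped or lay within 1 kb of an end of a protein-coding gene, against 26.4% of regions not called, an odds ratio of 0.185 (95% interval 0.167 to 0.206, Fisher's exact test). Of the gained regions 53.8% lay inside a gene, as at Tcf7 and Havcr2, and 40.0% between genes, as near Pparg. Lost regions sat at gene ends in 1103 of 2791 cases (39.5%), an odds ratio of 1.82 (1.68 to 1.97). The latter reversed with the loess offset (0.428) and without naive replicate 1 (0.438). There was no association without effector replicate 2 (0.969, 0.874 to 1.07) or effector replicate 1 (1.16, 0.916 to 1.46). Which end of a gene holds its promoter is not given in the gene table used, and regions are not independent replicates.

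The comparison of memory with naive cells asks what papain leaves behind after 2 months of rest. No PBS group rested for 2 months was among the 6 libraries, so effects of papain and of the elapsed time cannot be told apart. Few regions were called in the fit without a replicate term. The clearest of those with a gene assigned lay in or near the transcription factor gene Bhlhe40, Fam185a, the calcium channel gene Itpr1 and Tnc, which encodes the matrix protein tenascin C. Each had an edgeR adjusted p of 0.000965. The region 37.4 kb from Bhlhe40 (6:108704355-108705194) rose from 5.76 ± 1.24 in naive to 27.0 ± 2.99 CPM in memory cells (SD, n = 2 per group), and was at 21.1 ± 6.13 in effector cells. The region inside Itpr1 (6:108337673-108339144) rose from 5.89 ± 1.64 to 22.3 ± 1.08, and a region 23.6 kb from Tnc (4:63935185-63936228) rose from 16.2 ± 2.24 to 47.8 ± 8.86. A region inside Cd24a, which encodes a glycosylated surface protein, fell from 7.48 ± 1.53 to 2.15 ± 0.457. The edgeR test called 139 regions more and 40 less accessible in memory cells, of which 114 and 34 changed at least 2-fold. At an unadjusted p under 0.05 there were 2586 and 2958, and DESeq2 called 278 and 80. With the replicate number as a block edgeR called 868 and 766, though no label says what a shared number means.

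The leading gains lay in or near Bhlhe40, Fam185a, Tnc, Itpr1, Trps1, Arhgap15, Adap1, Sncaip, Gypc and Il1r2, the last encoding the decoy IL-1 receptor. Their log2 fold changes ran from 1.10 to 2.22 and their edgeR adjusted p from 0.000965 to 0.00384. The leading losses lay in or near Sardh, Creb3l1, Slc8a1, Zc3h12c, Efnb2, 1700017B05Rik, Cd24a, Prokr2, Sgk1 and Hhip, with log2 fold changes from −1.94 to −1.03 and edgeR adjusted p from 0.00785 to 0.0288. Of the regions with no gene within 100 kb, which were not ranked, 1 gain (13:83119880-83121264, edgeR adjusted p = 0.000658) and 1 loss (19:15751420-15752746, log2 −1.48, edgeR adjusted p = 0.00525) had a smaller adjusted p than any of these, and both are named after their values were seen. Among regions of the fixed lists, a region inside Tcf7 (11:52273676-52276123) rose from 10.7 ± 0.125 to 24.1 ± 5.37 CPM and a region 25.3 kb from Il10 (1:130993064-130994528) from 12.5 ± 2.51 to 33.0 ± 5.44 (edgeR adjusted p = 0.0216 and 0.00452). A region inside Cdk6 rose by 1.34 ± 0.27 on the log2 scale (SE), a region 9.1 kb from Il17a by 1.61 ± 0.30 and a region inside Pecam1 by 0.73 ± 0.15 (edgeR adjusted p = 0.0397, 0.0294 and 0.0412). Neither the Tcf7 nor the Il10 region here is the region that rose in effector cells.

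These calls leaned on few libraries. Without memory replicate 2 there were 14 gains and 0 losses, without naive replicate 1 there were 30 and 3, without naive replicate 2 there were 92 and 43, and without effector replicate 1 there were 137 and 23, while without memory replicate 1 there were 267 and 123. Of the 25 regions named in this comparison 17 lost their call in at least 1 of the 6 fits without a library, and none reversed. Those at Bhlhe40, Fam185a, Tnc, Itpr1, Trps1, Arhgap15, Adap1 and Sncaip kept it in every such fit. Without memory replicate 2 the edgeR adjusted p was 0.0561 for Gypc, 0.0577 for Il1r2, 0.0848 for Il10, 0.365 for Tcf7, 0.373 for Il17a, 0.385 for Cdk6, 0.374 for Pecam1 and 0.318 for Cd24a. For the other leading losses it lay between 0.116 for Sardh and 0.366 for Hhip. Without naive replicate 1 it was 0.0658 for Il10, 0.158 for Tcf7, 0.243 for Il17a, 0.159 for Cdk6, 0.315 for Pecam1 and 0.202 for Cd24a. Without naive replicate 2 it was 0.0818 for Tcf7, 0.0513 for Il17a, 0.156 for Cdk6 and 0.12 for Pecam1. The Cdk6 and Pecam1 calls also ended under total counts alone (0.0503 and 0.0614), TMM on the highest regions (0.0583 and 0.0738), without robust estimation (0.0555 and 0.0637) and with only the 2 groups fitted (0.0509 and 0.0511), and that of Pecam1 under the loess offset (0.0586).

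Lists of genes shifted slightly where single regions were rarely called. Regions of type 2 cytokines and effector products were higher in memory than naive cells as a list, with 79.6% of 113 regions above 0, a median log2 difference of 0.20 and a camera adjusted p of 2.36e-08. The list was not called with an estimated correlation (camera adjusted p = 0.273) or by fry (adjusted p = 0.154), and 0 of its regions were called singly by edgeR (10 rose and 0 fell when adjusted over the list alone). The mean over the regions of a gene was highest for Il6 (0.86), Penk (0.75), Il13 (0.67) and Csf2 (0.48), at 0.16 for Il5 and 0.08 for Il9 and Il2, and below 0 for Il4 (−0.02), Areg (−0.23) and Il3 (−0.26). The most covered Il13 region measured 38.4 ± 0.701 in naive and 55.1 ± 1.42 CPM in memory cells (SD, n = 2). That region was not called (edgeR adjusted p = 0.122). Markers of ILC3s, with 17 regions, had a median of 0.52 and a camera adjusted p of 1.29e-06 (adjusted p = 0.392 with an estimated correlation), with 1 region called (Il17a) and 7 when adjusted over the list alone. ILC2 transcription factors (median 0.10) and cell cycle genes (0.11) each had a camera adjusted p of 0.00777 (adjusted p = 0.392 and 0.273 with an estimated correlation). They had 2 and 1 regions called, and 9 gains and 0 losses and 6 gains and 1 loss when adjusted over the list alone. Both lost their call without memory replicate 2 (camera adjusted p = 0.0841 for both), and cell cycle genes also without naive replicate 2 (0.124). With regions at gene ends alone the ILC3, transcription factor and cell cycle lists were not called (0.504, 0.553 and 0.534), and the type 2 list was (0.00694).

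The other 16 lists had camera adjusted p from 0.0665 for mast cells and basophils (median −0.19) and 0.0734 for B cells (−0.22) to 0.904 for glycolysis and lipid metabolism (−0.01), SWI/SNF genes (−0.01) and the interferon response (0.04). Single calls in them were the Il10 region among inhibitory genes, the Tcf7 region among memory and quiescence genes and the Pecam1 region among endothelial markers. Medians were 0.04 for alarmin and cytokine receptors, −0.06 for AP-1 and NF-kB genes, −0.01 for inhibitory genes, 0.05 for neuropeptide receptors, 0.02 for residence genes, −0.07 for memory and quiescence genes and 0.01 for housekeeping genes. For markers of T cells, NK cells and ILC1, myeloid cells and lung structural cells they were −0.04, −0.05, −0.02 and −0.13. Median and mean differed in sign for the residence, interferon, NK cell and housekeeping lists. Against matched random lists the type 2, ILC3 and transcription factor medians lay at percentile 100 and cell cycle genes at 99.8, while AP-1 and NF-kB genes lay at 0, memory and quiescence genes at 0.1 and mast cells and basophils at 0.7. Of the memory gains 6 of 139 (4.3%) lay at a gene end, against 24.8% of regions not called (odds ratio 0.137, 95% interval 0.0494 to 0.306, Fisher's exact test). Without memory replicate 2 the odds ratio was 0.513, with a wide interval that includes 1 (0.0557 to 2.3). Of the losses 11 of 40 (27.5%) lay at a gene end (odds ratio 1.15, 0.519 to 2.38), an interval too wide to exclude an association. This odds ratio was 2.01 without naive replicate 2 and 1.59 without memory replicate 1. It was 0.645 without effector replicate 1, 0.664 without effector replicate 2, 0.818 with RLE size factors and 0.92 within 3 kb of a gene end, and these 4 intervals include 1. With the replicate number as a block it was 1.40 (1.20 to 1.64, 766 losses).

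**Figure D3:**
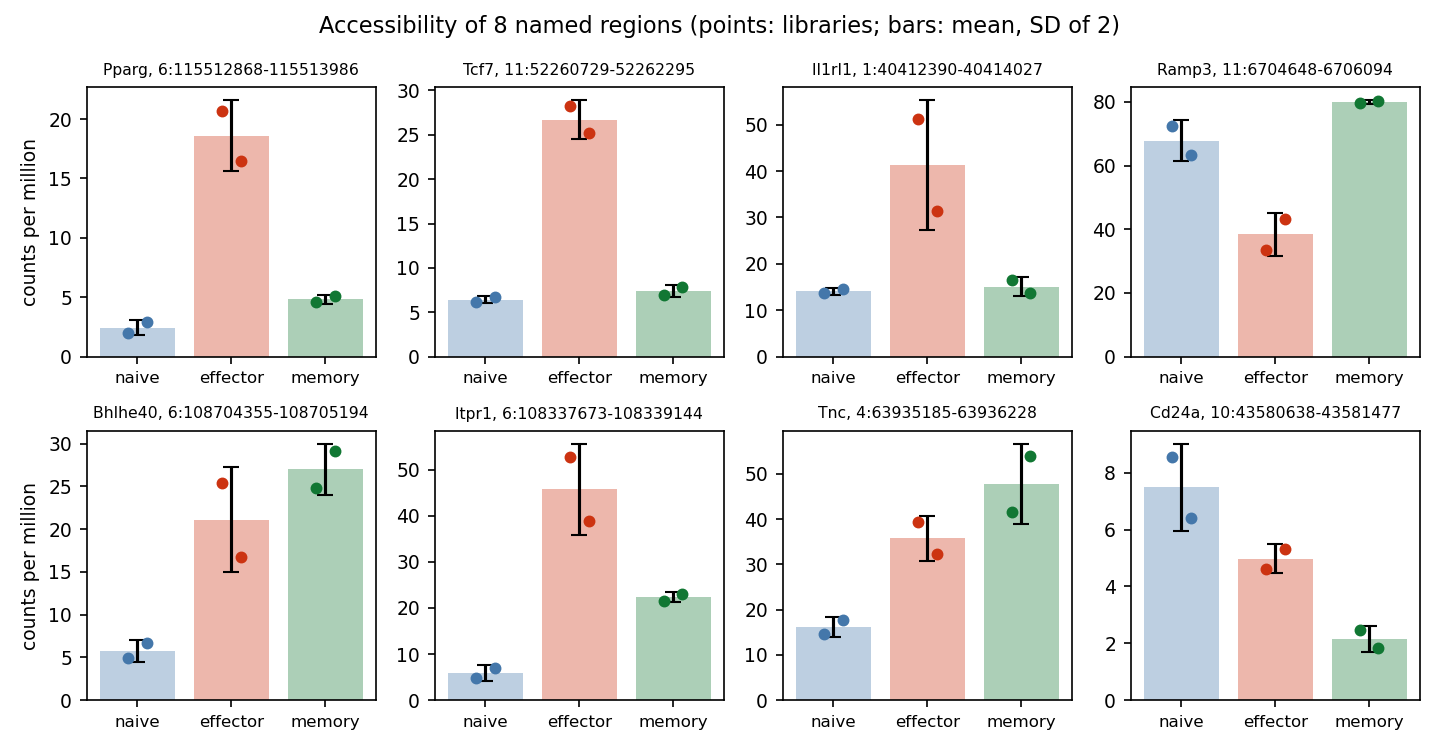
CPM, scaled by TMM, of 8 named regions in each library (points), with bars for the mean of the 2 libraries of a group and error bars for their SD. The region near Bhlhe40 averages 5.76, 21.1 and 27.0 in naive, effector and memory cells, and the region near Pparg 2.44, 18.6 and 4.85.

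The comparison of memory with effector cells asks how far the papain state fades with rest. The regions that had opened near Pparg, Tcf7, Il1rl1 and Havcr2 were lower in memory cells, and those that had closed near Adora2a and Ramp3 were higher. The region near Pparg fell from 18.6 ± 2.98 to 4.85 ± 0.379 CPM (SD, n = 2 per group), and the region inside Havcr2 from 30.2 ± 4.91 to 9.64 ± 0.958. The region near Ramp3 (11:6704648-6706094) rose from 38.4 ± 6.81 to 79.9 ± 0.583. The edgeR test called 4322 regions more and 7634 less accessible in memory than effector cells, of which 611 and 6400 changed at least 2-fold. Calls of at least 2-fold numbered 347 more and 7289 less with total counts alone, 1098 and 3957 with the loess offset and 204 and 8664 with TMM on the highest regions.

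The leading falls lay in or near Foxb2, Stard9, Abcb8, Tprg, E130308A19Rik, Ngef, Map4k3, Lactb, Adarb1 and Msmo1, with edgeR adjusted p from 7.74e-07 to 3.97e-06. The region 24.3 kb from Foxb2 held 548 effector and 3 memory counts, a ratio of 176 (95% counting interval 59.9 to 856), and that inside Abcb8 held 767 and 20, a ratio of 36.9 (23.7 to 60.8). For the other 8 the log2 fold changes ran from −4.43 to −2.32. The leading gains lay in or near Slc27a6, Rnf125, Erich2, Ppm1k, Adgrl2, Ccdc71l, Tdrd5, Ptcd3, Tmem38b and Prdm10, with log2 fold changes from 1.05 to 2.32 and edgeR adjusted p from 2.56e-05 to 5.91e-05.

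Effector products, receptors and regulators moved both ways. Of 113 type 2 regions 13 rose and 11 fell (14 and 11 when adjusted over the list alone). Regions near Calca, the gene of calcitonin and CGRP, and Il2 rose by 1.06 ± 0.15 and 0.69 ± 0.12 on the log2 scale (SE), and a region near Lif had a log2 fold change of −1.96 ± 0.28. The region at Gzmb held 174 effector and 18 memory counts, a ratio of 9.31 (95% counting interval 5.72 to 16.1). Of 366 ILC2 transcription factor regions 25 rose and 44 fell (23 and 40 when adjusted over the list alone), including a region 91.5 kb from Gata3 (2:9764297-9765597) at −2.41 ± 0.38. Of 139 receptor regions 11 rose and 15 fell (11 and 13 when adjusted over the list alone), with Il4ra at −2.60 ± 0.39 and the IL-10 receptor gene Il10ra at 0.92 ± 0.16. Of 221 AP-1 and NF-kB regions 16 rose and 36 fell (24 and 38 when adjusted over the list alone), with Nfkbiz, an NF-kB regulator, at −1.68 ± 0.19. Of 163 inhibitory regions 15 rose and 31 fell (18 and 33 when adjusted over the list alone), with Entpd1, which encodes CD39, at −2.12 ± 0.32. Of 97 neuropeptide receptor regions 11 rose and 6 fell (11 and 6 when adjusted over the list alone), with Ramp3 at 1.06 ± 0.14.

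Of 243 memory and quiescence regions 18 rose and 58 fell (19 and 61 when adjusted over the list alone). A region inside Foxp1, a quiescence factor gene, had a log2 fold change of −2.01 ± 0.27 (SE), and the region near Id3 held 234 effector and 6 memory counts, a ratio of 37.6 (95% counting interval 17.0 to 103). Of 126 residence regions 14 rose and 21 fell (14 and 23 when adjusted over the list alone), with the chemokine receptor gene Ccr9 at −2.51 ± 0.34. Of 88 cell cycle regions 6 rose and 10 fell (6 and 10), of 111 glycolysis and lipid regions 9 rose and 13 fell (9 and 12), of 97 SWI/SNF regions 6 rose and 9 fell (5 and 7) and of 32 interferon regions 1 rose and 2 fell (1 and 2), each followed by the counts when adjusted over the list alone. The region inside Arid1b had −2.63 ± 0.36. For the marker lists the calls were 3 up and 7 down for T cells (3 and 7), 0 and 2 for B cells (0 and 1), 1 and 2 for NK cells and ILC1 (3 and 2), 3 and 1 for ILC3s (6 and 1), 2 and 8 for myeloid cells (2 and 8), 3 and 2 for mast cells and basophils (3 and 2), and 1 and 8 for lung structural cells (1 and 6). Housekeeping regions had 7 up and 6 down (7 and 6). Over all regions 7.7% rose and 13.6% fell. Camera called 0 of 20 lists (lowest adjusted p 0.137, for neuropeptide receptors, median 0.17), also with an estimated correlation. Fry called that list upwards and the myeloid list downwards (adjusted p = 0.0176 for both). Against matched random lists the transcription factor, AP-1 and NF-kB and inhibitory medians lay at percentile 0 and memory and quiescence genes at 1.4, while ILC3 markers lay at 99.9, cell cycle genes at 98.7 and neuropeptide receptors at 98.3. Median and mean differed in sign for the type 2, receptor, cell cycle, interferon, mast cell and housekeeping lists, for example 0.09 and −0.04 for type 2 genes.

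The most covered regions of Il17rb, a receptor chain for IL-25, and Areg were higher in memory than effector cells by 0.93 ± 0.27 and 0.49 ± 0.13 on the log2 scale (SE, edgeR adjusted p = 0.0229 and 0.0138). Those of Klrg1 and the costimulator gene Icos had log2 fold changes of −0.54 ± 0.15 and −0.64 ± 0.14 (edgeR adjusted p = 0.0175 and 0.00449). These calls were lost without effector replicate 1 for Il17rb (0.144), Areg (0.166) and Klrg1 (0.219), and without memory replicate 2 for Il17rb (0.159), Areg (0.0655), Klrg1 (0.174) and Icos (0.064). Il17rb also lost its call without effector replicate 2 (0.062), and it and Areg did so under total counts alone (0.0567 and 0.0539) and TMM on the highest regions (0.103 and 0.195), as did Areg under the loess offset (0.229). For Il5, Il13, Il4, Gata3, Rora, Il1rl1, Tcf7 and Smarca4 the edgeR adjusted p lay between 0.0877 and 0.534.

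Gains were 36.1% of these calls with TMM, 18.8% with total counts alone (2051 more, 8857 less) and 8.3% with TMM on the highest regions (1002 more, 11052 less), and the median of all regions was −0.04, −0.16 and −0.28. With the loess offset there were 2336 more and 5390 less, and without effector replicate 1 there were 971 and 3327, without effector replicate 2 2881 and 5410, and without memory replicate 1 2154 and 5864. Regions that fell lay at a gene end in 720 of 7634 cases (9.4%, odds ratio 0.294, 95% interval 0.271 to 0.318, Fisher's exact test), as the Havcr2 and Pparg regions did not. Regions that rose did so in 1592 of 4322 cases (36.8%, odds ratio 1.64, 1.54 to 1.76), as at Il2. The latter reversed with the loess offset (0.276) and without memory replicate 1 (0.764). There was no association with total counts (0.984, 0.889 to 1.09), without effector replicate 1 (0.902, 0.774 to 1.05) or without effector replicate 2 (0.946, 0.867 to 1.03).

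Setting the comparisons together shows how many of the changes called in effector cells were still measurable in memory cells. Without a rested PBS group, fading of a papain effect cannot be told apart from other changes over the 2 months. Of the 6449 regions gained in effector cells, 4972 (77.1%) were called lower in memory than effector cells without a call above naive, as at Pparg and Havcr2. A further 110 were still called above naive, as at Bhlhe40, Itpr1 and Trps1, and 15 of those were also below effector cells, as at Itpr1. The other 1367 had neither call. Gains and losses were chosen on the same 2 effector libraries that memory cells are then compared with. Chance deviations of these libraries would therefore add to the calls back towards naive. Regions chosen on 1 replicate and measured on the other, given below, are free of this. The median log2 fold change of the gained regions was 1.73 in effector and 0.14 in memory cells, the latter 0.42 without naive replicate 2, 0.26 without naive replicate 1, 0.23 without effector replicate 1 and 0.09 without memory replicate 2. Of the 2791 lost regions 1984 (71.1%) were called higher in memory than effector cells, as near Adora2a and Ramp3, 7 were still below naive, as near Creb3l1, and 800 had neither call, with medians of −0.60 and −0.02. The last ran from −0.17 without naive replicate 2 to 0.04 without memory replicate 2, and the 71.1% fell to 33.9% without memory replicate 1. The 110 regions were among the 139 memory gains, where 16 would be shared by independent lists of these sizes, and for the losses 7 were shared against 2. With the replicate number as a block 524 gains and 185 losses were shared, against 135.8 and 89.7 for independent lists.

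Both comparisons use the same 2 naive libraries. Dividing these would leave each comparison 1 control, so they were kept together, and part of the excess may come from the shared controls. In 10 simulated sets with no difference between groups, at most 16 and 17 regions were called and at most 5 were shared. Across regions the log2 differences of effector and memory from naive cells correlated at 0.203, against 0.505 in 100 such simulations, with a covariance of 0.073 against 0.065. All groups were unchanged in these sets, whereas many regions differed in effector cells. Such a change lengthens the effector list and lowers the correlation. The simulated shared calls and correlation therefore do not bound the part due to shared controls. Regions chosen on 1 replicate and measured on the other had median log2 differences of 1.45 and 1.76 in effector cells and −0.05 and 0.04 in memory cells for gains. For losses these were −0.44 and −0.65 in effector cells and −0.19 and −0.04 in memory cells. The count of gains still called was 14 without memory replicate 2, 27 without naive replicate 1, 70 without effector replicate 1 and 201 without memory replicate 1, and DESeq2 gave 196. Each fit without a library called its own sets of gains and losses, so counts called back towards naive do not compare between these fits. Without effector replicate 1 the gained regions had medians of 2.04 in effector and 0.23 in memory cells. The lost regions had memory medians of −0.05 without effector replicate 1, −0.04 without naive replicate 1, −0.17 without naive replicate 2 and −0.1 without memory replicate 1. Their effector medians there were −0.78, −0.88, −0.75 and −0.58. Losses still called numbered 0 without naive replicate 1, effector replicate 1 or memory replicate 2, and 20 without memory replicate 1.

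**Figure D4:**
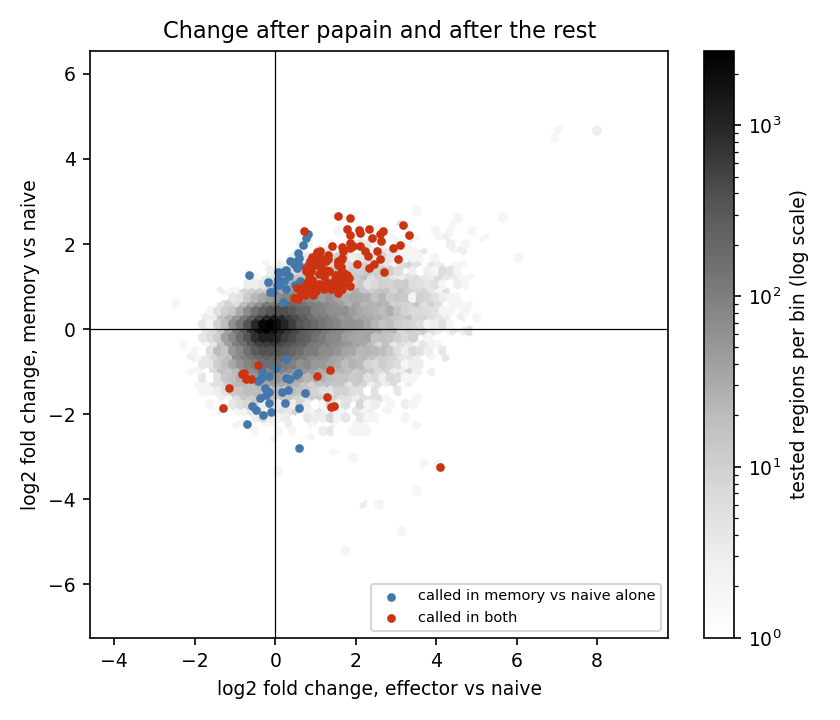
Log2 fold change against naive cells in effector (x axis) and memory cells (y axis), with grey shading for the number of tested regions per bin on a log scale, blue points for regions called in memory against naive cells alone and red points for regions called in both comparisons. Most red points lie above 0 on both axes, where 110 regions were called higher in effector and in memory cells, and the 6 red points right of and below 0 were called higher in effector and lower in memory cells.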

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

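The test of marker lists for the gains in effector cells was chosen, and its bounds set, only after its result was seen. The other tests of explanations in this part were planned.

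In 6 regions effector cells were called above naive and memory cells below naive (edgeR adjusted p for memory against effector, which follows in part from the opposite signs, between 7.74e-07 and 2.17e-05). There were 0 such regions without naive replicate 1, effector replicate 1 or memory replicate 2, 1 without naive replicate 2 or with only the 2 groups fitted, 4 without effector replicate 2, 15 without memory replicate 1, 13 with DESeq2, 10 with total counts, 9 with the loess offset, 11 with TMM on the highest regions and 0 at an adjusted p under 0.01. The log2 fold changes against naive in effector and memory cells were 1.47 and −1.81 inside Vps53, 1.36 and −0.97 near Map4k3, 1.39 and −1.83 at Slc1a1, 1.04 and −1.11 inside Flnc, and 1.29 and −1.61 near Rybp. The region near Foxb2 had too few memory counts for a fold change (3 counts, against 548 in effector cells). These regions, except those near Map4k3 and Foxb2, lie outside the naming rule and were chosen after their values were seen. They are 6 of 40 memory losses, and effector gains made up 11.5% of all tested regions, so independent lists would also share a few.

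Effector cells gained many more regions than they lost among changes of at least 2-fold (5342 and 387, 93.2% gains), as they did without effector replicate 1 (2339 and 73) and effector replicate 2 (4268 and 823). A lower signal over background in the effector libraries would lift regions with few counts, but with a loess offset that removed the fall of the log2 fold change with abundance there were 3907 gains and 707 losses, still 84.7% gains, which argues against the trend as the whole cause and not as a part. Chromatin of another cell type in the effector pools stays open: the highest of 7 marker lists, ILC3s, lay at percentile 97.1 of matched lists, short of the bound for a cause and above the bound against it, a bound that was lowered after this value was seen and under whose first version the value would have counted against. Myeloid markers, at percentile 67, were called upwards by fry (adjusted p = 0.0284) and downwards in memory against effector cells (adjusted p = 0.0176), and camera called neither. The Lin-CD25+ST2+ gate is meant to leave out such cells, but the purity of the sort was not examined. Of the 3 called ILC3 regions those near Il17f and Il22 rose and that inside Il1r1 fell, with each call lost without some library. Of the 6 ILC3 genes 5 had regions, and none is in another list. A response of the cells to papain may account for the gains but was not separated from these explanations.

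As a list, type 2 cytokine and effector genes were higher in memory than naive cells by a median log2 of 0.20. An abundance trend is argued against, since the median stayed at 0.18 with the loess offset (camera adjusted p = 2.53e-07). That a few loci with many neighbouring regions alone carry the direction is argued against, since 17 of 20 genes (85%) had a mean above 0 (exact binomial p = 0.00258, two-sided). The binomial test takes genes as independent and ignores size. Means were 0.86 for Il6 (10 regions) and 0.48 for Csf2 (12 regions), but 0.06 for Gzmb and 0.08 for Il2, Il9 and Lif. The size was thus uneven, and Il6, Csf2 and Ccl1 (0.31, 12 regions) weighed most on the list mean of 0.24. How far the shift remains without these loci was not tested. What stays open is that regions of a list vary together, since with an estimated correlation the list was not called (camera adjusted p = 0.273), and the mice of the memory group were also sampled 2 months later. Chromatin of other cells stays open too, since ILC3 markers, alone of the 7 marker lists, lay above the central 95% of matched lists (median 0.52, matched −0.22 to 0.17, percentile 100), with a camera adjusted p of 1.29e-06, or 0.392 with an estimated correlation. A lasting effect of papain at these genes may be a hypothesis, found and tested on the same libraries.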

How the results depend on the processing

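All alternatives here were planned except TMM on the 20% highest regions, which was chosen after seeing the data. No count of calls, list or odds ratio is given for motif content or for GC and width, which were not run. With RLE size factors or no low-count filter every count of calls, memory state, odds ratio and list count stayed on its side and within 1.5 times, with 2 exceptions. The odds ratio of memory losses, 1.15, was 0.818 with RLE (neither called). Without the filter 1 region lost in effector cells was called above naive in memory cells, against 0 with it. In what follows counts are more and less for effector against naive, memory against naive and memory against effector. The cause of a difference between settings was not tested, except that an adjusted p under 0.01, a 2-fold minimum and fewer libraries select or measure less by construction.

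Total counts gave 1535 losses in effector cells and 2051 gains over effector, the loess offset 1625 and 2336, and TMM on the highest regions 739 and 1002. DESeq2 gave 278 and 80 calls in memory against naive cells. Without robust estimation and with only 2 groups fitted, losses there were 20 and 22. An adjusted p under 0.01 gave 3746 and 740, 36 and 3, and 1358 and 4332. A minimum of 2-fold gave 387 losses in effector cells and 611 gains over effector.

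With the replicate block, where libraries share only a number, there were 8765 and 6555, 868 and 766, and 8352 and 10240 calls, 524 gains and 185 losses were still called in memory cells, 4863 losses were called higher again, 109 gains were called below naive in memory cells, and the odds ratio of memory losses at gene ends was 1.40. Deviations of same-numbered libraries correlated at 0.24, 0.27 and 0.19 across regions.

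Gains still called in memory cells numbered 196 with DESeq2 and 27 at 0.01, and gains called lower again 2740 of 3746 at 0.01. Losses still called numbered 3 without robust estimation, 1 at 0.01 and 4 with TMM on the highest regions. Losses called higher again numbered 940 of 1535 with total counts and 917 of 1625 with the loess offset. They numbered 509 of 740 at 0.01 and 404 of 739 with TMM on the highest regions. In the hold-out the gains chosen on replicate 1 had a memory median of −0.05, below 0, against 0.04 the other way round. The odds ratio at gene ends reversed with the loess offset for effector losses (0.428) and for gains over effector (0.276), which showed no association with total counts (0.984). Lists called numbered 0, 4 and 0. With an estimated correlation 0 were called in memory against naive cells. With fry there were 1, 0 and 2, and with gene end regions alone 1 in effector and 1 in memory against naive cells.

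Leaving out each library in turn gave 2530 to 7000 gains and 377 to 3331 losses in effector cells, 14 to 267 and 0 to 123 in memory against naive, and 971 to 4145 and 3327 to 7940 in memory against effector cells. Gains still called ran from 14 to 201 and called lower again from 1757 to 4166, losses still called from 0 to 20 and called higher again from 234 to 1902. Odds ratios ran from 0.135 to 0.199 and 0.438 to 2.39 for effector gains and losses (reversed at 0.438, no association at 0.969 and 1.16), 0.165 to 0.513 (not called at 0.513) and 0.645 to 2.01 for memory against naive (below 1 but not called at 0.645 and 0.664), and 0.764 to 2.13 (reversed at 0.764, no association at 0.902 and 0.946) and 0.212 to 0.312 for memory against effector. Lists called ran from 3 to 5 in memory against naive cells. Of the named regions 22 of 84, 17 of 25 and 25 of 95 lost a call without some library and none reversed. Small changes may be missed, since 4.5% of 67 simulated 1.5-fold changes were recovered at this depth and with 2 libraries per group. Neither depth nor the number of libraries was varied.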

Other observations

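The counts of neighbouring regions per gene and of regions called in memory cells against both other states were made only after the calls were seen, and so were the names below.

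Gained regions clustered at some genes. Of 6531 genes with at least 3 tested regions, 20 held an excess of gained regions in effector cells at an adjusted p under 0.05 (one-sided hypergeometric test). Each gene was set against the 12.8% gained among the regions of these genes, and genes above that share but past no threshold are not counted. Etv6, which encodes a transcriptional repressor, had 19 of 39 regions gained, Tnfsf4, which encodes OX40 ligand, 9 of 10, Gm52481, near the end of chromosome Y, 9 of 10 (median log2 2.47), Mefv, which encodes the inflammasome protein pyrin, 7 of 7, Fto 9 of 12 and Rptor, which encodes a subunit of the kinase complex mTORC1, 10 of 15. The labels give female mice unless otherwise stated, and whether the Gm52481 regions share sequence with chromosome X was not examined. In memory against naive cells Itpr1 had 5 of 40 and Tnc 3 of 5 regions gained, and Cd24a 2 of 3 lost. In memory against effector cells 15 genes held an excess of falling regions at the same threshold, including Foxp1 with 21 of 41 and Mefv with 7 of 7. Regions of a gene are not independent, so these counts describe clustering and are no test of a gene.

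Some regions were called in memory cells against both other states. Both comparisons use the same 2 memory libraries, whose chance deviations alone would give joint calls, and no value for unchanged groups was made. There were 31 regions called higher in memory than in naive and in effector cells, 25 of them with no call between effector and naive. These include the region 25.3 kb from Il10 (1:130993064-130994528), the region inside Tcf7 (11:52273676-52276123) and the region near Il17a. There were 33 regions called lower in memory cells than in both, 26 of them with no call between effector and naive, among them the region inside Cd24a (10:43580638-43581477). The memory calls at these 4 were lost without memory replicate 2, where memory cells had only 14 gains and 0 losses against naive cells in all, and without naive replicate 1 there were 30 and 3.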
